A study of Mus musculus with 3 samples.

How the data were processed

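RNA-seq of brain vessels from 3-month-old mice was analysed in 3 libraries: Cx43-deleted on a C57BL6-BALB/c background, WT C57BL6-BALB/c and WT C57BL6, 1 library each. Groups came from the labels. Whether a library was made from 1 animal or a pool is not given in the sources used here.

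The authors deposited, for each library, a table of 82813 Ensembl transcripts with a whole-number read count, per the file headers. The count had not been normalised. A second column deposited by the authors gives each count as a fraction of 1 total per library, and dividing the count by that fraction gave the library totals of 54975610 (Cx43-deleted), 21170766 (WT C57BL6-BALB/c) and 24830975 (WT C57BL6). The other columns used are the length of the transcript and the number of its bases with no read, per the file headers. A read was counted on every transcript it overlapped: the counts sum to 2.55, 2.53 and 2.45 times the library totals. Counts of transcripts of a gene are therefore not independent, and overlapping or antisense genes share reads, since the library kit named in the labels' protocols (TruSeq RNA v2) does not keep the strand. CASAVA 1.8.2, Bowtie and the build mm10 are named in the submitters' processing notes. The version of Bowtie, the counting program, the annotation release and the treatment of reads with several matches are not given in the sources used here.

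The coordinates in the deposited tables reach 197054592 on chromosome 1, beyond the last gene of that chromosome in the GRCm38 annotation at 195323493, so they are of an older build and were not used. Transcript identifiers were matched to GENCODE M21 on GRCm38, from which all names and positions come: 69379 of 82813 matched (83.8%), 217 of these were on another chromosome than in the tables and were left out, and 13434 did not match. The matched transcripts carried 83.4%, 83.4% and 84.0% of the counts. Leaving out the 217 was decided after the data were seen.

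Counts were summed over the transcripts of a gene and divided by the library total times a TMM factor (0.976, 1.00 and 1.02; edgeR 4.0.16 in R 4.3.3), giving CPM. Log2 ratios were taken with a pseudocount of 0.5, which understates the ratio of low genes. Genes with a level of 1 or more in at least 1 library were kept, 16594 of 29775. A level of 1 is 53.6, 21.2 and 25.4 counts summed over transcripts in the 3 libraries, which can be fewer reads, since a read may be counted on several transcripts of a gene. The floor of 3 reads on a single transcript is a level of 0.0559, 0.141 and 0.118. Folds with intervals were computed from the reads of the most abundant transcript with exact binomial 95% intervals, in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3; against 0 reads the fold is a lower bound from the floor of 3 reads per library.

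No test was possible with 1 library per group, and no p-value is given. A gene was counted when its log2 ratio was 1 or more, and the distance to both other libraries is the ratio to the nearer one. For 38 gene lists the median log2 ratio was set against 10000 random lists of the same size matched on mean level in 20 bins. Intervals of list medians are order-statistic intervals over genes. Over all genes, 33.2% lay above both WT libraries and 35.6% below both, where chance gives 33.3%. The groups, comparisons, lists, size rule, naming rule and all but 2 of the alternatives were fixed before the data were examined. Older symbols in the lists that the annotation has renamed, such as that of Ccn1, were not measured under the list.

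Named over all genes were the 15 with the largest ratio above both WT libraries, with a level of 5 or more in the Cx43-deleted library, and the 15 furthest below both, with a level of 5 or more in both WT libraries. Between the WT libraries it was the 10 furthest each way, with a level of 5 or more in the higher one. Predicted genes, pseudogenes, and ribosomal, small RNA and other multicopy genes were not to be named among these. The exclusion worked by symbol and annotation type, which does not recognise other multicopy genes, so the IgG and Serpina3 genes, Cwc22 and Sfi1 stayed and are called uncertain. In each list, Gja1 and up to 4 members furthest outside both WT libraries could be named, along with any member 2-fold or more from both and all members of the sex-linked, strain and neighbour lists. Genes named in the closing section for a hypothesis, and the genes of the plot of levels, were chosen after values had been seen.

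The steps were tested on simulated Poisson counts for 16171 genes from the means and totals of these libraries. Of 50 genes simulated 4-fold up and 50 simulated 4-fold down in the Cx43-deleted library, 100% and 100% were counted beyond both WT libraries. Of the genes simulated at 1.5-fold, 0% were counted, and 0 of 15971 unchanged genes were. The simulation holds counting error only, without variation between animals.

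Alternatives, whose effects the closing section gives, were pseudocounts of 0.1 and 1, a minimum level of 5 or none, median-of-ratios size factors (DESeq2 1.42.0), scaling by total, the most abundant transcript of a gene, 10 bins for random lists, and lists without genes shared with other lists. Thinning the Cx43-deleted library to the total of WT C57BL6-BALB/c and list medians relative to the endothelial list were added after the data were seen.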

Results

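RNA from brain vessels of 3-month-old mice was sequenced in 3 libraries, 1 for each group. In the first group the connexin 43 gene (Gja1) was deleted in astroglia by a Cre recombinase under the human GFAP promoter, on a mixed C57BL6-BALB/c background. The other groups were wild-type (WT) mice of that mixed background and WT C57BL6 mice. The library totals were 54975610 reads for the Cx43-deleted library, 21170766 for WT C57BL6-BALB/c and 24830975 for WT C57BL6. With 1 library per group there were no replicates and no test, so each difference below is a difference between libraries. Levels are normalised counts (CPM) summed over the transcripts of a gene. Read numbers and folds are those of its most abundant transcript, the folds with 95% counting intervals. These intervals, and the floors of 3 reads, cover counting error only. Where 3 values are given, they are in the order Cx43-deleted, WT C57BL6-BALB/c, WT C57BL6.

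Gja1 (ENSMUSG00000050953; GRCm38 chromosome 10, 56377330 to 56402513) encodes connexin 43, the gap junction protein of astrocytes and their perivascular endfeet. Its level was 48.0 in the Cx43-deleted library and 202 in each WT library, from 2574, 4276 and 5138 reads. It was 4.20-fold lower than in WT C57BL6-BALB/c (4.001 to 4.41) and 4.21-fold lower than in WT C57BL6 (4.02 to 4.42), a log2 ratio of −2.06 in each case. Of the 3071 bases of its transcript, 6 had no read in the Cx43-deleted library, 1 in WT C57BL6-BALB/c and 0 in WT C57BL6.

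The comparison of the Cx43-deleted library with the WT libraries asks how brain vessel transcripts, immune genes among them, differ when astroglia lack connexin 43. Immunoglobulin transcripts were the furthest above both WT libraries among the named genes. Igkc, the kappa light chain constant gene, had 4849 reads against 150 and 46, which is 12.8-fold (10.9 to 15.1) above WT C57BL6-BALB/c and 49.9-fold (37.4 to 68.3) above WT C57BL6. Ighg1, a heavy chain constant gene of IgG, had 4100 reads against 10 and 1, a 162-fold difference (88.0 to 338) from WT C57BL6-BALB/c. Jchain, which joins the subunits of polymeric antibodies, was 5.52-fold (4.29 to 7.22) and 9.15-fold (6.82 to 12.5) higher. Ighm, the constant gene of IgM, went the other way, with a level of 7.51 against 28.2 and 21.8.

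Other IgG genes lay on the side of Ighg1. Ighg2b had 626 reads against 1 and 0, which is 247-fold (44.3 to 9790) above WT C57BL6-BALB/c and at least 98.8-fold higher than in WT C57BL6. Ighg3 had 416 reads against 2 in each WT library, 82.2-fold (22.6 to 681) above WT C57BL6-BALB/c. The heavy chain constant genes resemble each other and differ between mouse strains, so the split of reads among them is uncertain.

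Serpina3n, a secreted serine protease inhibitor of reactive astrocytes, had a level of 84.2 against 14.9 and 16.8, and was 5.67-fold (5.06 to 6.38) above WT C57BL6-BALB/c. Serpina3i of the same gene cluster was at 5.39 against 0.519 and 0.630, with 279, 11 and 8 reads on its most abundant transcript, and reads shared within the cluster make both values uncertain. Pmaip1, a pro-apoptotic BH3-only protein, was at 62.6 against 3.82 and 7.83. Fkbp5, a co-chaperone of the glucocorticoid receptor, was at 315 against 97.9 and 51.4. Rdh13, a retinol dehydrogenase, was at 247 against 59.5 and 76.9. Prm1, a sperm nuclear protein, had 313 reads against 8 and 0. Ubtd2, Cd300lf, Gdpd3 and Chrdl2 had log2 ratios to the nearer WT library of 2.03, 1.96, 1.65 and 1.53.

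Immediate early genes, which cells transcribe within minutes of a stimulus, were lower in the Cx43-deleted library as a group. Of 28 measured members, 25 lay below both WT libraries, 12 of them by 2-fold or more, and 0 lay above both. Fos was 7.77-fold (7.21 to 8.39) below WT C57BL6-BALB/c and 6.02-fold (5.58 to 6.50) below WT C57BL6. Egr1 was at 84.5 against 245 and 255, Nr4a1 at 172 against 535 and 458, and Junb at 21.8 against 52.7 and 55.0. Fosb was at 7.66 against 284 and 37.9, so it also differed between the WT libraries. The other members at 2-fold or more were Egr2, Egr3, Egr4, Nr4a2, Ier2, Btg2 and Atf3, with log2 ratios to the nearer WT library of −1.65, −1.06, −1.21, −1.12, −1.002, −1.25 and −1.02. The list median was −0.81 against WT C57BL6-BALB/c and −1.19 against WT C57BL6, and −0.31 between the WT libraries. Against 10000 random lists of like expression, the first pair of medians lay at percentile 0.00 and the WT pair at 0.02, given as a description of these libraries. Smooth muscle markers were also lower, with a median of −0.82 against WT C57BL6-BALB/c, where 20 of 20 were lower, and −0.46 against WT C57BL6. Of the 20, 18 were below both. Between the WT libraries smooth muscle markers went the other way from the immediate early list, with a median of 0.32 and 17 of 20 higher in WT C57BL6-BALB/c.

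Other genes far below both WT libraries were of several kinds. Rec8, a meiotic cohesin subunit, had 26 reads against 306 and 338, 29.8-fold (19.9 to 46.3) and 27.4-fold (18.4 to 42.6) lower. Ccn1, a secreted matrix protein, was at 25.3 against 95.8 and 195, and Thbs1, thrombospondin, at 20.2 against 61.9 and 55.4. Hjurp, a chaperone of centromeric histones, was at 156 against 544 and 562, and Pttg1, securin, at 21.0 against 75.0 and 316. Capn11 and Olfml2a had log2 ratios of −1.61 and −1.40 to the nearer WT library. Hspa8, a heat shock cognate protein, was at 38.9 against 155 and 219, but its most abundant transcript was only 2.52-fold (2.31 to 2.75) and 3.72-fold (3.44 to 4.02) lower, and processed pseudogenes make these values uncertain.

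**Figure D1:**
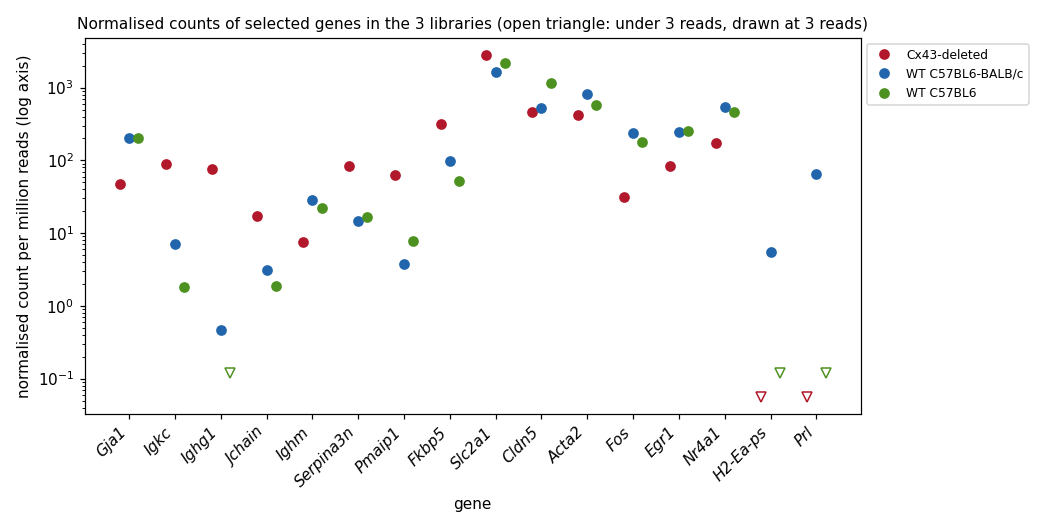
Normalised counts (CPM, log axis) of 16 genes in the 3 libraries; each point is 1 library, and an open triangle marks a gene with under 3 reads, drawn at the level of 3 reads. The genes plotted were chosen after their values were seen; Igkc stands at 90.4 in the Cx43-deleted library against 7.07 and 1.81, and Fos at 31.5 against 239 and 178.

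Over all 16594 measured genes, 71 were at least 2-fold above both WT libraries and 63 at least 2-fold below both. The same counts for WT C57BL6-BALB/c against the other libraries were 56 and 59, and for WT C57BL6 they were 164 and 57. Against WT C57BL6-BALB/c alone, 175 genes were higher and 168 lower, and against WT C57BL6 alone, 256 were higher and 484 lower. With a minimum level of 5, the genes above both others numbered 42 for the Cx43-deleted library and 35 for WT C57BL6-BALB/c, and those above WT C57BL6-BALB/c alone 113. With a pseudocount of 0.1, the genes below both others numbered 96 for the Cx43-deleted library, 105 for WT C57BL6-BALB/c and 119 for WT C57BL6, so the order of these counts depends on the pseudocount. Without regard to size, 33.2% of genes lay above both WT libraries and 35.6% below both, against the 33.3% that chance gives.

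Of 26 endothelial markers, 16 lay below both WT libraries and 1 above both, 0 of them by 2-fold. Their median was −0.14 against WT C57BL6-BALB/c, with an interval of −0.28 to 0.02 and 10 members higher, and −0.75 against WT C57BL6 (−0.98 to −0.55). Tek, an angiopoietin receptor, was at 467 against 676 and 1054, and Kdr, a VEGF receptor, at 129 against 185 and 309. Slc2a1, the glucose transporter of the barrier endothelium, was the member above both, at 2828 against 1653 and 2162. The WT libraries differed from each other by −0.66 on the same list.

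Of 27 tight and adherens junction genes, 18 were below both WT libraries and 3 above both, with medians of −0.18 against WT C57BL6-BALB/c and −0.42 against WT C57BL6. F11r, Cldn3, Cdh5 and Cgnl1 were at −0.49, −0.37, −0.36 and −0.31 to the nearer WT library. Of 25 blood-brain barrier transporters, 6 were above both and 7 below both, with medians of 0.11 and −0.39. Slc16a1, a monocarboxylate transporter, was at 84.1 against 144 and 255. Slc38a5 and Slc40a1 had log2 ratios of −0.71 and −0.62 to the nearer WT library.

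In several immune groups most members lay below both WT libraries, as did most endothelial markers. Of 25 leukocyte adhesion molecules, 19 were below both WT libraries and 0 above both, with medians of −0.20 and −0.81. Mcam was at 311 against 582 and 572, and Sele, E-selectin, at 0.447 against 1.27 and 1.77. Of 44 interferon-stimulated genes, 30 were below both and 0 above both, with medians of −0.12 and −1.03, and Gbp4 was at 47.2 against 81.3 and 112. All 44 were highest in WT C57BL6, so none could lie above both, and 14 were higher than in WT C57BL6-BALB/c. Of 22 MHC class I genes, 15 were below both and 2 above both, with medians of −0.19 and −0.80, and H2-T23 was at 16.9 against 31.4 and 42.4. Of 27 NF-kB genes, 18 were below both and 2 above both, with medians of −0.13 and −0.54, and Ptgs2, a prostaglandin synthase, was at 33.9 against 135 and 53.1. Of 24 acute-phase and reactive glia genes, 15 were below both and 2 above both, with medians of −0.24 and −0.77. In that list Emp1 was at 93.0 against 273 and 193, and Serpina3n lay on the other side. Relative to the endothelial median, the interferon list was at 0.02 and the NF-kB list at 0.01 against WT C57BL6-BALB/c. The WT libraries also differed on these lists without the deletion. WT C57BL6-BALB/c to WT C57BL6, the adhesion and interferon medians were −0.40 and −0.84. The MHC class I, NF-kB and acute-phase medians were −0.53, −0.36 and −0.27.

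Soluble mediators were mostly at low levels. Of 22 cytokines, 11 were below both WT libraries and 6 above both, with medians of −0.08 and −0.24. Il1b was at 0.485 against 1.70 and 2.05, and Il18 at 28.0 against 13.6 and 17.04. Of 21 chemokines, 10 were below both and 4 above both, with medians of −0.11 and −0.44, and Ccl2 was at 0.895 against 3.54 and 2.01. Of 35 cytokine and chemokine receptors, 19 were below both and 4 above both, with medians of −0.07 and −0.54, and Cxcr4 was at 10.6 against 20.7 and 26.2. Of 12 MHC class II genes, 2 were above both and 2 below both, with medians of 0.26 and −0.28. Cd40 was at 6.49 against 11.8 and 17.5, and H2-DMa at 15.99 against 14.9 and 13.5. Of 21 complement genes, 6 were above both and 8 below both, with medians of 0.09 and −0.25. C1qbp was at 32.7 against 39.8 and 47.5, and C4b at 37.6 against 26.3 and 26.1. Cfd had 132 reads against 0 in both WT libraries, at least 17.4-fold higher than in WT C57BL6-BALB/c and at least 20.8-fold higher than in WT C57BL6.

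Markers of immune and blood cells went in different directions. Of 17 perivascular macrophage markers, 6 were above both WT libraries and 5 below both, with medians of 0.29 and −0.37. Cd163, a haemoglobin scavenger receptor, was at 32.4 against 16.9 and 16.6, Siglec1 at 9.10 against 4.67 and 6.18, and Cbr2 at 16.1 against 22.4 and 21.1. Of 25 microglia markers, 12 were below both and 0 above both, with medians of 0.01 and −0.58. The first was −0.03 under scaling by total. All 25 were lower than in WT C57BL6, and 13 were higher than in WT C57BL6-BALB/c. The WT libraries differed by −0.60 on this list. Of 17 neutrophil and monocyte markers, 14 were below both and 1 above both, with medians of −0.30 and −0.91, the latter −0.49 without a filter on low levels, and Ltf, lactoferrin, was at 1.44 against 9.57 and 3.27. Of 17 T and NK cell markers, 7 were below both and 2 above both, with medians of −0.08 and −0.26. Foxp3 in that list shares 31.5% of its exon bases with other genes and is uncertain. The 13 B and plasma cell markers, with Igkc and Jchain among them, had medians of −0.24 and −0.27, since 9 were below both and 3 above both. Of 8 red blood cell genes, 7 were below both and 0 above both, with medians of −0.30 and −1.21, and Hbb-bs, a beta globin, was at 231 against 292 and 509.

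Of 30 astrocyte markers, 19 were below both WT libraries and 4 above both, with medians of −0.13 and −0.36, and Sox9 was at 24.5 against 33.8 and 42.5. Of 22 endfoot and dystroglycan complex genes, the deleted Gja1 included, 12 were below both and 5 above both, with medians of −0.18 and −0.27. Mlc1 was at 166 against 243 and 304, and Kcnj10, a potassium channel of endfeet, at 117 against 148 and 147. Of 11 connexins and pannexins, Gja1 included, 8 were below both and 2 above both, with medians of −0.09 and −0.46, and Gja5, an arterial endothelial connexin, was at 16.7 against 35.3 and 33.9. Of 20 smooth muscle markers, 18 were below both and 0 above both, with medians of −0.82 and −0.46. Map3k7cl and Ppp1r14a were at −0.71 and −0.64 to the nearer WT library, and Pln, 64.7% of whose exon bases overlap other genes, is uncertain. Of 20 pericyte markers, 12 were below both and 0 above both, with medians of −0.08 and −0.83, and Cspg4 was at 56.2 against 109 and 100.1. All 20 pericyte markers were lower than in WT C57BL6, and 8 were higher than in WT C57BL6-BALB/c. The WT libraries differed by −0.65 on that list. Of 31 basement membrane and matrix genes, 20 were below both and 3 above both, with medians of −0.14 and −0.39, and Bgn was at 305 against 472 and 544. Of 24 fibroblast markers, 13 were below both and 7 above both, with medians of −0.04 and −0.33. Lum, lumican, was at 8.85 against 16.3 and 21.1, Dcn, decorin, at 57.8 against 92.8 and 103, and Col6a1 at 443 against 315 and 225. Of 37 Wnt and Notch genes, 22 were below both and 6 above both, with medians of −0.14 and −0.44, and Heyl was at 24.7 against 44.4 and 69.7.

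The remaining lists mark other cell types and general processes. Neuron markers had medians of −0.11 against WT C57BL6-BALB/c and 0.27 against WT C57BL6, with 11 of 30 above both and 12 below both. Oligodendrocyte markers were at −0.05 and −0.35, with 14 of 25 below both and 3 above both. Choroid plexus and ependyma markers were at 0.16 and −0.75, with 11 of 25 below both and 0 above both. All 25 of the latter were lower than in WT C57BL6, and 14 were higher than in WT C57BL6-BALB/c. The WT libraries differed by −0.66 on that list. Stress genes were at −0.02 and −0.50, with 15 of 27 below both and 1 above both. Oxidative phosphorylation genes were at −0.01 and −0.41, with 25 of 46 below both and 8 above both, and cytosolic ribosomal proteins at 0.04 and −0.06, with 13 of 50 above both and 10 below both. Of 26 cell cycle genes, 12 were above both and 9 below both, with medians of 0.17 and −0.0018, the latter 0.02 with median-of-ratios size factors. Bub1b, a mitotic checkpoint kinase, was at 33.0 against 0.943 and 16.1, Birc5, survivin, at 5.54 against 3.30 and 2.48, and Kif11, a mitotic kinesin, at 1.58 against 4.15 and 4.68. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had reads in all 3 libraries, Xist was at 1.12, 1.08 and 1.81, and the medians of the sex-linked list were 0.07 and 0.19. The 4 measured genes that differ by strain had medians of −0.20 and 0.04. Their values ran from −3.57 to 0.33 against WT C57BL6-BALB/c, so the median says little about them. The 18 neighbours of Gja1 on chromosome 10 had medians of −0.08 and −0.14, with 10 below both and 3 above both, and Fabp7, a fatty acid binding protein of glia, was at 4.57 against 10.47 and 11.2.

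Of the 38 lists, 15 had a median in the lowest 2.5% of random lists against both WT libraries and 0 in the highest 2.5% against both. The 15 were the endothelial, junction, adhesion, MHC class I, interferon, NF-kB, acute-phase, astrocyte, endfoot, basement membrane, smooth muscle, neutrophil, red blood cell, immediate early, and Wnt and Notch lists. Between the WT libraries, 28 of the 38 lists were outside the same bounds. Among these 15, relative to the endothelial median, the astrocyte list was at 0.01 and 0.39 and the basement membrane list at 0.0034 and 0.36. The Wnt and Notch list was at 0.0022 and 0.31 and the NF-kB list at 0.01 and 0.21, so the sign of these lists turned. The interferon list turned against WT C57BL6-BALB/c only, at 0.02. Against WT C57BL6-BALB/c these values are small beside the interval of the endothelial median itself (−0.28 to 0.02). There these lists lay about at the endothelial median. Against WT C57BL6 the sign also turned for the junction list at 0.33, the endfoot list at 0.48 and the smooth muscle list at 0.29.

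**Figure D2:**
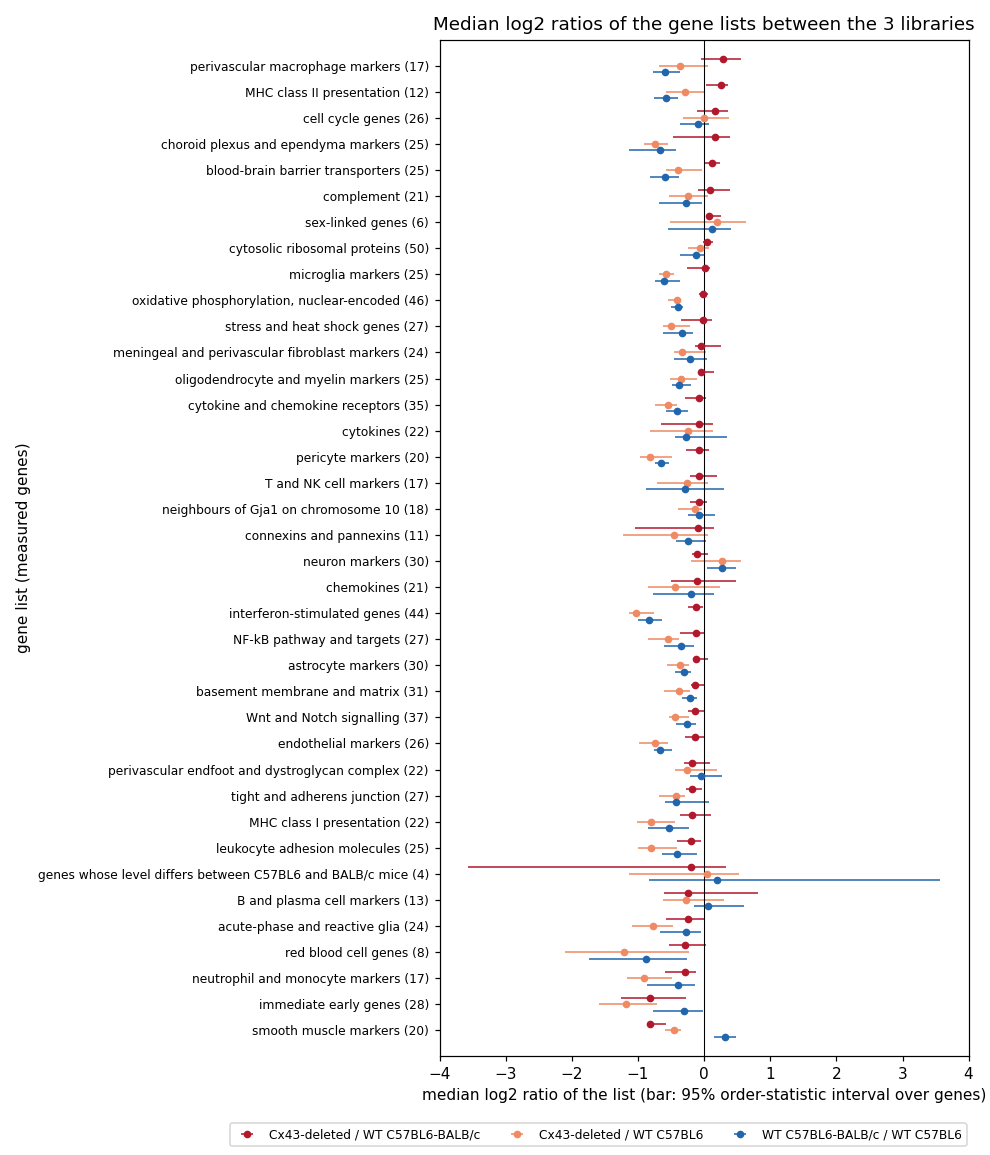
Median log2 ratio (horizontal axis) of each gene list for the 3 pairs of libraries, with the number of measured genes; bars are 95% order-statistic intervals over the genes of a list. Immediate early genes are at −0.81 and −1.19 against the WT libraries, and smooth muscle markers at −0.82 and −0.46 while they are at 0.32 between the WT libraries.

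The comparison of the WT libraries shows how far libraries of different background differ without the deletion. The pituitary hormone genes Prl, Cga and Gh were the furthest higher in WT C57BL6-BALB/c among the named genes. Prl, prolactin, had 684 reads there, 1 in the Cx43-deleted library and 0 in WT C57BL6. Gh, growth hormone, had 933 reads there against 2 and 7 in the other libraries, and Fshb had 140 against 3 and 0. Cga had 518 reads against 19 and 2, but 32.0% of its exon bases overlap Platr9, which had 246 against 7 and 3. H2-Q10, an MHC class I gene, had 361 reads against 8 and 6. Nlrp1a had 57 against 1 and 2, uncertain because of its near-copy Nlrp1b. Cwc22, at 57.6, 369 and 47.4 with 135, 1395 and 43 reads on its most abundant transcript, and Sfi1, at 1379.8, 5485 and 957, have several copies in mouse genomes and are uncertain.

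Higher in WT C57BL6 than in WT C57BL6-BALB/c were Tnni1, a slow muscle troponin, at 15.7 against 0.849, and Myoc, myocilin, at 107 against 9.01. Lcn2, lipocalin, was at 643 against 99.3, and Omp, olfactory marker protein, at 7.16 against 0.707. Bub1b was at 16.1 against 0.943 and stood at 33.0 in the Cx43-deleted library. Kcnj15, Col6a4 and Btnl9 had log2 ratios of −2.19, −2.17 and −2.16 between the WT libraries, and Ang and Nlrp1b, uncertain because of Rnase4 and Nlrp1a, −2.95 and −2.49. In all, 195 genes were at least 2-fold higher in WT C57BL6-BALB/c and 346 at least 2-fold lower; the first count was 120 with a minimum level of 5 and 298 with a pseudocount of 0.1. Interferon-stimulated genes were at −0.84, endothelial markers at −0.66 and smooth muscle markers at 0.32. The 4 measured genes that differ by strain had a median of 0.19, over values from −0.83 to 3.57. Among them H2-Ea-ps had 115 reads in WT C57BL6-BALB/c and 0 in both other libraries, and Ly6a was at 207, 257 and 458.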

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

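Of the tests in this part, that of plasma cell genes was written down before its result was seen; those of Igkc and Jchain, Ighg1, red blood cell genes, neuron, smooth muscle, endothelial and interferon lists, and libraries per group were chosen after, the smooth muscle test in place of one between the WT libraries, which do not hold the pattern. Some differences lay outside the gene table, among the deposited transcripts whose identifiers did not match the annotation. Of these, 29 were at least 2-fold above both WT libraries in the Cx43-deleted library. Of these unmatched transcripts 16 were 2-fold below both, of 8281 with a level of 1 or more, and none was used in the comparisons. The same counts were 19 and 19 for WT C57BL6-BALB/c and 48 and 38 for WT C57BL6, so those of the Cx43-deleted library do not stand out.

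Immunoglobulin and J chain transcripts stood higher in the Cx43-deleted library. A difference in Igh alleles would by itself leave Igkc and Jchain, which lie outside that locus, alike. The lowest 95% counting bound of their log2 ratios was 2.10. These ratios are the ones for which both genes were flagged, so the bound restates the pattern and is no separate test. It also covers counting error only. For the IgG genes an allele difference stays open, since no value separates allele from expression. Ighg1 differed by 0.85 between the WT libraries, but this rests on 10 and 1 reads and is too uncertain to bear on it. Blood left in the vessels would raise red blood cell genes about as much as Igkc (3.59), and the upper end of the interval of their median against WT C57BL6-BALB/c was 0.028; this bound, under 1, was the second tried after the result was seen, since the first, an interval below 0 against both WT libraries, decided nothing with a median of −0.30. Plasma cells in the tissue may contribute and cannot be told apart from the deletion or a difference between animals: 33.3% of 12 independent plasma cell genes lay above both WT libraries (exact interval 9.92% to 65.1%), which meets the bound set beforehand against them but not by more than its spread, and Xbp1, Ssr4 and Txndc5 on that list are abundant in all 3 libraries.

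Immediate early genes were lower in the Cx43-deleted library. Fewer neurons in the preparation would lower neuron markers as well, and their median against WT C57BL6 was 0.27 (−0.20 to 0.55), with a lower end of −0.18 against WT C57BL6-BALB/c, above the immediate early medians. Fewer smooth muscle cells would lower these genes by no more than smooth muscle markers. Against WT C57BL6 the interval of the immediate early median ended at −0.72, below that of smooth muscle markers (−0.60 to −0.36). Immediate early genes were thus lower by more than smooth muscle markers between these libraries. The intervals are over genes, with 1 library per group, and hold no variation between animals, so they do not decide the cause. Against WT C57BL6-BALB/c the medians were alike, −0.81 with an interval up to −0.27 and −0.82. By single genes, 13 of 28 immediate early genes and 3 of 20 smooth muscle markers were lower there by 2-fold or more. Fewer smooth muscle cells therefore stay open as a cause of the median, but the like medians do not cover the members that were lower by more. Handling of the animal or tissue could set the immediate early genes too. With 1 library per group these causes cannot be told apart from the deletion, which stays open and untested.

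Interferon-stimulated genes were higher in WT C57BL6 than in both other libraries. A larger share of endothelial cells in that library could contribute: the interferon median exceeded the endothelial one in size, by −0.28 between the Cx43-deleted and WT C57BL6 libraries, but the intervals of the medians overlapped. The mixed-background libraries differed by −0.12 on this list, less than either did from WT C57BL6 (−1.03 and −0.84), which background could give too. Only 1 library has the C57BL6 background, so background and any other feature of that library cannot be told apart.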

How the results depend on the processing

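Thinning the Cx43-deleted library and medians relative to the endothelial list were chosen after the data were seen. Of the recomputed counts and Gja1 ratios, 104 stayed within 1.5 times (counts) or shifted by at most 0.5 of the width of the counting interval (Gja1), and 8 did not; of the recomputed ratios of named genes to the nearer WT library, 1612 shifted by at most 0.5 of the width of the counting interval and 18 by more, with 0 reversed among those called. With a pseudocount of 0.1, genes higher in WT C57BL6-BALB/c than in WT C57BL6 were 298, and those lower than both other libraries 96 (Cx43-deleted), 105 (WT C57BL6-BALB/c) and 119 (WT C57BL6); a smaller pseudocount enlarges the ratios of low genes. With a minimum level of 5, fewer genes were measured: 113 were higher in the Cx43-deleted library than in WT C57BL6-BALB/c, 120 higher in WT C57BL6-BALB/c than in WT C57BL6, and 42 and 35 higher in the Cx43-deleted and WT C57BL6-BALB/c libraries than in both others. Without a filter the neutrophil and monocyte median against WT C57BL6 was −0.49, where more genes of low level entered; the cause was not tested. Pseudocount 1, no filter, size factors, total scaling, the most abundant transcript and thinning moved none of the counts by over 1.5 times, and 10 bins moved no list percentile by 5 or more. The deposited fractions are scaling by total by construction and were not run separately.

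Relative to the endothelial median, which subtracts a fixed value from each list, the direction turned, among the 15 lists in the lowest 2.5% against both WT libraries, for junction genes against WT C57BL6 (0.33), interferon genes against WT C57BL6-BALB/c (0.021), NF-kB genes (0.011 and 0.21 against WT C57BL6-BALB/c and WT C57BL6), astrocyte markers (0.011 and 0.39), endfoot genes against WT C57BL6 (0.48), basement membrane genes (0.0034 and 0.36), smooth muscle markers against WT C57BL6 (0.29), and Wnt and Notch genes (0.0022 and 0.31). The values of 0.021 or less against WT C57BL6-BALB/c are small beside the interval of the endothelial median itself (−0.28 to 0.02). There those lists lay about at the endothelial median. Direction was not judged for the other lists, several of which changed sign. Other values against WT C57BL6-BALB/c that shifted by more than 0.5 of the width of their interval were junction genes −0.045, transporters 0.25, neuron markers 0.033, oligodendrocyte markers 0.086, oxidative phosphorylation 0.13, ribosomal proteins 0.18, sex-linked genes 0.21 and Gja1 neighbours 0.054. Against WT C57BL6 these were transporters 0.36, adhesion −0.061, chemokines 0.31, cytokines 0.51, receptors 0.21, MHC class I −0.048, MHC class II 0.47, interferon −0.28, complement 0.50, acute-phase −0.025, connexins 0.29, pericytes −0.077, fibroblasts 0.42, microglia 0.17, macrophages 0.38, T and NK cells 0.48, B and plasma cells 0.48, neutrophils −0.16, neurons 1.02, oligodendrocytes 0.40, choroid plexus 0.00074, immediate early −0.44, stress 0.25, cell cycle 0.75, oxidative phosphorylation 0.34, ribosomal proteins 0.69, sex-linked 0.94 and Gja1 neighbours 0.61. Immediate early genes stayed lower than both WT libraries under all settings run. Depth limits the low genes: the Cx43-deleted library has 2.60 and 2.21 times the reads of the WT libraries, and a gene at a level of 1 rests on at most 21.2 reads in WT C57BL6-BALB/c, and on fewer where a read is counted on several of its transcripts.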

Other observations

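The tests in this part, of pituitary genes, H2 region genes and glucocorticoid-induced genes, were written down before their results were seen, though on patterns already noticed in these data; the comparison of the H2 region between the WT libraries was added after. Omp and Tnni1, genes of olfactory and muscle tissue, stood at 7.16 and 15.7 in WT C57BL6 against 0.707 and 0.849 in WT C57BL6-BALB/c. Myoc stood at 107 against 9.01 in the same libraries.

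A hypothesis is that the WT C57BL6-BALB/c library may hold some pituitary tissue. Prl and Gh stood at 64.5 and 44.0 there. Of 10 independent pituitary genes with reads, 70.0% had their highest level in that library (exact interval 34.8% to 93.3%), against 33.3% by chance. Gnrhr had 12 reads there and 0 in both others, and Lhb was at 8.54 against 3.49 and 5.43. The bound set beforehand was 2 in 3. Several of the 10 rest on few reads, such as Ghrhr with 3, Lhb and Trhr were read in all libraries, and Neurod4, Foxl2 and Pou1f1 were highest in the Cx43-deleted one.

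A hypothesis is that the WT C57BL6-BALB/c and Cx43-deleted mice may differ in H2 haplotype, since H2-Ea-ps had 115 reads in the first and 0 in the second. Over 121 genes of the H2 region (GRCm38 chromosome 17, 33996017 to 37483552), the median absolute log2 ratio between these libraries was 0.23, at percentile 99.8 of random lists. This passes the bound set beforehand. Between the WT libraries, where H2-Ea-ps differs as much, the median was 0.25 at percentile 16.9, and between the Cx43-deleted and WT C57BL6 libraries 0.32 at 53.5. These medians are no smaller, but random lists differ more between those libraries, so the region did not stand apart there. The question stays open, and it bears on how well WT C57BL6-BALB/c matches the Cx43-deleted mice at that region.

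A hypothesis is that Fkbp5 may mark a glucocorticoid response in the Cx43-deleted library. Zbtb16, Hif3a and Map3k6 were noticed with Fkbp5, but their values are not given here. Of 12 independent glucocorticoid-induced genes, 33.3% lay above both WT libraries, the share that chance gives (exact interval 9.92% to 65.1%). This meets the bound set beforehand against the hypothesis, but not by more than its spread. Their median was 0.51 against WT C57BL6-BALB/c, at percentile 100 of random lists, and −0.03 against WT C57BL6, at percentile 41.3. The median depends on which WT library is used, and the test did not decide.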
